A study of Poecilia mexicana x Poecilia latipinna and Poecilia formosa with 28 samples.

How the data were processed

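Messenger RNA of brain, liver and ovary was sequenced from females of a clonal P. formosa line and of 1 brood of F1 hybrids between a P. mexicana female and a P. latipinna male, per the labels' protocols. Fish of the 2 groups were matched for size and age, kept alike, and untreated. RNA was extracted with TRIzol, treated with DNase and used only with an integrity number above 8, and libraries followed the TruSeq mRNA protocol, per the labels. The kit's handling of strand was not given in the sources used here, so overlapping genes on opposite strands cannot be told apart.

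The authors deposited a single table of raw read counts per gene for the 28 libraries, with 31997 genes and no normalization. The submitters' processing notes name TopHat2, a spliced read aligner, and featureCounts, which assigns reads to genes, without their settings. The genome build and the annotation were not given in the sources used here. Reads of hybrids carry alleles of 2 species, and a reference of another genotype can take up reads of the groups unequally. Genes with near-identical copies can share or lose reads, so a gene with no count in 1 genotype may have an allele that was not counted. The columns were matched to the samples by name, and 0 columns of per-sample values were left unused. The table held whole numbers with different totals per library, from 32460110 to 46316691, which fits raw counts.

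Genes carry numeric IDs that the table does not pair with names, and no table of names or genome was used here. The lists of pathways and cell types fixed before the data were examined, the organ marker genes and the rule that named genes by symbol could therefore not be run. In their place, for each organ, the 2 genes with the largest positive and the 2 with the largest negative log2 fold change are given by ID, among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the genotypes. For genes shared by the organs, 2 per direction were taken. Genes were also put into classes, chosen after seeing the data: brain-enriched (2807 genes), liver-enriched (1619) and ovary-enriched (2141) had a mean of at least 5 CPM in that organ and at least 4 times the mean of either other organ, with both genotypes weighted equally. Broadly expressed genes (5052) had at least 5 CPM in each organ and differed by less than 4-fold between organs. The classes were made from the same libraries as the tests and hold genes, not cell types.

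Groups were taken from the labels. Each organ was tested on its own libraries with edgeR 4.0.16 in R 4.3.3: low genes were removed with filterByExpr, libraries were scaled with TMM, and the robust quasi-likelihood test compared P. formosa with hybrids, with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are P. formosa minus hybrid. CPM of single genes and median levels of classes used library totals scaled by TMM. Numbers of genes at 1 CPM or more, and of genes counted in 1 genotype only, used plain totals. The interaction of genotype and organ was tested in 1 fit of 6 groups over all 28 libraries. Class tests used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, in limma 3.58.1 on voom values, adjusted over the 12 tests of 4 classes in 3 organs, and class medians are medians of the limma fold changes. The spread between siblings used genes with a mean of at least 5 CPM, log2 CPM with a prior count of 2, and a correction for group size. It was tested with an exact two-sided permutation test over all splits of the fish. The splits exchanged finished values without new group means. Values of fish in a group are coupled through that mean, so the p-values are approximate. A fold against a group with no count is a lower bound against 3 counts over that group, and with 1 to 3 counts the ratio has a 95% exact interval. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

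The library numbers in the labels fall into 2 series: the P. formosa fish and hybrids 4 and 10 belong to the first, and hybrids 11 to 14 to the second. The labels do not call this a batch, and the main tests had no term for it. As an alternative it was treated as a batch, with the series as a term in the model. The genotypes are then compared within the first series, which rests on hybrids 4 and 10, while the spread comes from all libraries. No 2 libraries of a group were alike within sampling noise: the lowest chi-square per degree of freedom of any pair was 13.4, between P. formosa ovaries 4 and 12. Libraries of different organs that share a fish come from the same animal and are paired. Deviations of such libraries from their group means had a median correlation across genes of 0.11 between brain and liver, 0.11 between brain and ovary and 0.05 between liver and ovary. Numbers shared between P. formosa and hybrid fish name different animals.

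Tests were checked on simulated counts with 200 changed genes per simulation. Of 100 genes changed by 2-fold, 59 were recovered in brain (22611 genes simulated), 23 in liver (17402 genes) and 68 in ovary (22164 genes). Of 100 genes changed by 4-fold, 90, 86 and 96 were recovered, and false calls made up 5.10%, 3.54% and 4.65% of calls. Far more genes were called in the data (2727 in brain, 8129 in liver and 6052 in ovary). The simulated genes also varied independently and without a series difference. These shares therefore do not measure power or error in the data. In 100 simulations without a difference in sibling spread, 7 gave p under 0.05, and with a 1.5-fold difference all 100 did. These simulations used the liver layout and drew the deviation of each gene independently. They therefore do not measure error or power where genes of a fish deviate together. For the interaction of liver and ovary, 145 of 200 genes changed by 4-fold were recovered (24871 genes simulated). Counts were drawn with 1 spread per gene for all organs, as the fit assumes, so that assumption was not tested. Alternatives fixed before the data were examined covered other size factors, no filter and a stricter one, DESeq2 1.42.0, limma voom, the library series, a block, thresholds, the fish with all organs, and each fish left out in turn.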

Results

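The Amazon molly, Poecilia formosa, is an all-female fish that reproduces clonally and descends from a cross between Poecilia mexicana and Poecilia latipinna. The experiment set females of 1 laboratory clone, kept for about 70 generations, against females of 1 brood of F1 hybrids made by crossing the same 2 species in the aquarium. The comparison asks how gene expression of a long-established clonal hybrid differs from that of a first-generation hybrid of the same kind of cross. Messenger RNA from brain, liver and ovary was sequenced from 4 P. formosa fish and 6 hybrid fish, all 3 months old and untreated. For 2 of the hybrids (fish 11 and 14) no ovary library was analysed here, which leaves 28 libraries: 4 and 6 in brain, 4 and 6 in liver, and 4 and 4 in ovary. Fish of a group are siblings, so the p-values of gene tests cover only the spread among siblings of 1 clone and 1 brood. Camera with a preset correlation and the shuffles of genes compare genes with genes, so their p-values do not measure that spread.

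Total counts per library ran from 32460110 to 37706902 in brain, from 40586409 to 46316691 in liver and from 41249726 to 45987727 in ovary. Of the 31997 genes in the table, 3888 had no count in any library. Liver RNA was concentrated in few genes: the 10 most counted genes took 25.6% to 41.4% of a liver library, 3.46% to 5.53% of a brain library and 2.97% to 3.699% of an ovary library. P. formosa livers had 14128 ± 506 genes at 1 CPM (counts scaled to the library total) or more (SD, n = 4), and hybrid livers had 12614 ± 315 (SD, n = 6). The same number was 19766 ± 225 (n = 4) against 19196 ± 141 (n = 6) in brain, and 18334 ± 176 (n = 4) against 18275 ± 205 (n = 4) in ovary. The table names genes by numeric ID and does not pair the IDs with gene names, so gene groups are described by where they were expressed, and at most 2 IDs are given per direction in a comparison.

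Over all libraries the first 2 principal components of log2 CPM separated the 3 organs and held 56.8% and 32.9% of the variance. Within each organ the genotypes separated on the first component, which held 49.8% of the variance in brain, 60.1% in liver and 60.5% in ovary. In brain, P. formosa fish 11 and 4 lay at scores of -139 and -75.0, while P. formosa fish 3 and 12 lay at -11.5 and -20.7.

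**Figure D1:**
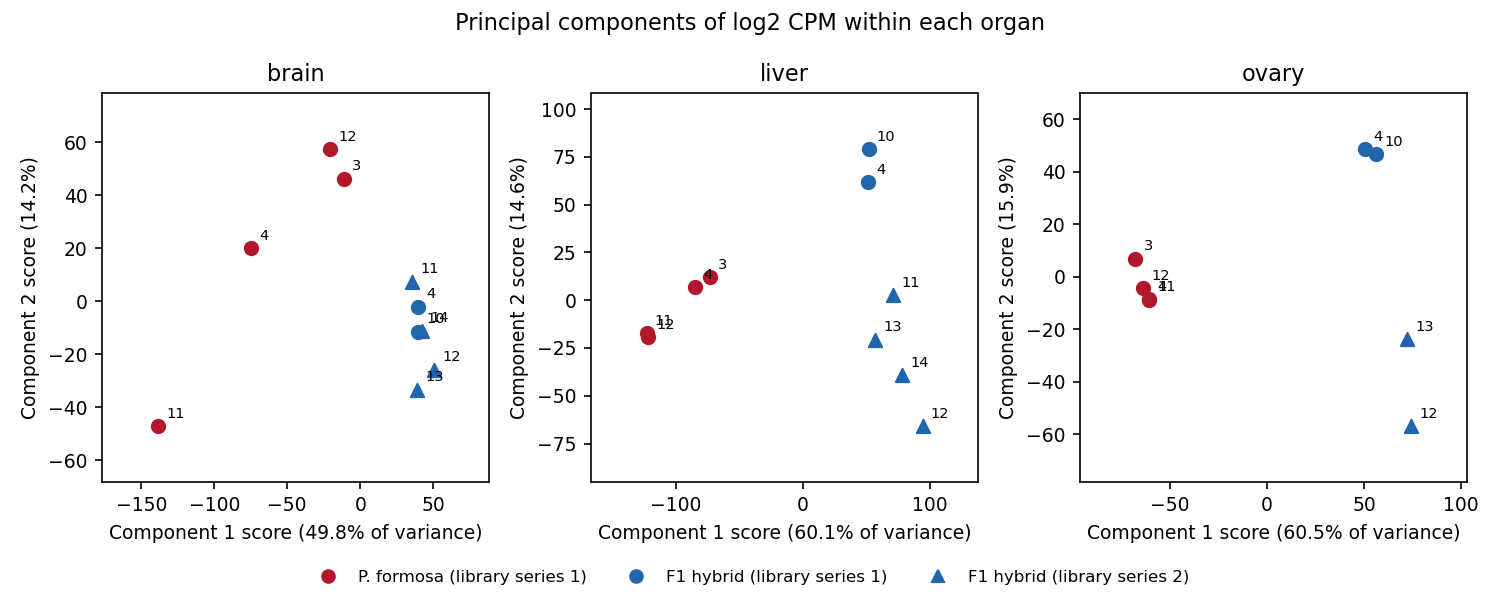
Scores of each library on components 1 and 2 of log2 CPM within its organ, with the share of variance on each axis; red points are P. formosa, blue points F1 hybrids, circles and triangles the 2 series of library numbers, and the small digits the fish numbers. The genotypes lie apart on component 1 in each organ, and in brain P. formosa fish 11 and 4 lie at -139 and -75.0.

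With all fish the liver had the most called genes. With hybrids of the second library series only, which leaves 2 hybrids in ovary, the ovary had 9374 and the liver 9059. All P. formosa libraries belong to the first series, so genotype and series cannot be told apart in these 2 counts. Of 17402 liver genes tested, 4213 were higher and 3916 lower in P. formosa than in the hybrids, 46.7% of those tested, and 3104 of the higher and 1968 of the lower genes differed by over 2-fold. Called genes of the other organs' classes were more often higher than lower in P. formosa liver. Of the 1349 tested genes enriched in brain over both other organs by at least 4-fold, 477 were higher and 103 lower, with a median log2 fold change of 0.58. Of 1524 ovary-enriched genes, 511 were higher and 162 lower (median 0.69). Among the liver's own enriched genes 173 of 1619 were higher and 467 lower (median -0.22), and of the 5052 genes expressed broadly in all organs 890 were higher and 1640 lower (median -0.19). The brain- and ovary-enriched genes were scarce in liver, with median levels of 1.21 and 2.18 CPM in P. formosa and 0.725 and 1.31 CPM in the hybrids, against 53.0 and 73.1 CPM for the liver-enriched genes.

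Each of the 4 classes differed from the other genes in liver by camera with a preset correlation of 0.01 (limma, adjusted p from 5.3e-05 to 0.0010). None of these calls held when the correlation between genes was estimated (adjusted p = 0.506 for the 3 enriched classes and 0.299 for the broad class). By fry, which asks whether a class moves one way on balance, adjusted p was 0.0049 for the brain-enriched, 0.0216 for the ovary-enriched, 0.0049 for the broad and 0.0547 for the liver-enriched genes. The calls by camera held with each library left out in turn. Gene 103154613 had a mean of 5.42 ± 0.85 CPM in P. formosa liver (SD, n = 4) and no count in the 6 hybrid livers, at least 450.5-fold higher. Gene 103144922 stood at 43.6 ± 15.4 CPM (n = 4) against 0.0229 ± 0.0298 (n = 6). In the other direction, gene 103131645 had 14.0 ± 2.52 CPM in hybrid liver (n = 6) and gene 103132985 had 8.08 ± 4.40 (n = 6), with no count of either in the 4 P. formosa livers, at least 872-fold and 493-fold lower. Adjusted p for these 4 genes lay between 1.7e-07 and 1.5e-04 (edgeR quasi-likelihood test). With upper-quartile factors in place of TMM, the liver split moved to 5023 higher and 3018 lower genes, 62.5% higher in place of 51.8%. The median of all liver genes shifted by 0.16 on the log2 scale. The medians of the liver-enriched and broad genes, -0.22 and -0.19, were of similar size to that shift. The class tests were not run with these factors, so the lower level of these classes and their fry p-values may depend on the scaling. With the library series as a term, the liver counts were 3229 and 3070, and 5145 genes were called in the same direction with and without it.

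**Figure D2:**
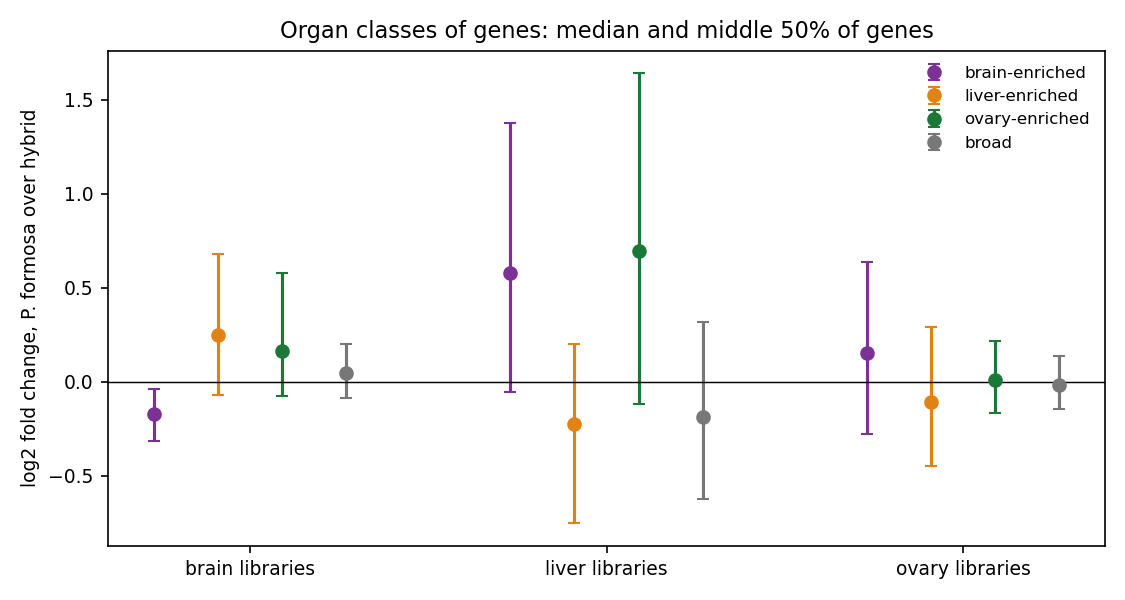
Log2 fold change of P. formosa over hybrid for 4 classes of genes in the libraries of each organ; points are medians over genes and bars the middle 50% of genes, not an error of the median. In liver the brain- and ovary-enriched classes have medians of 0.58 and 0.69 and the liver-enriched class one of -0.22; in ovary the 4 medians lie between -0.11 and 0.15.

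In the ovary, 3158 genes were higher and 2894 lower in P. formosa among 22164 tested, 27.3% of them, and most differences were small: the median size among called genes was 0.77 on the log2 scale, against 1.22 in liver and 1.17 in brain. Changes over 2-fold numbered 1307 and 1064. The ovary's own enriched genes were nearly balanced, with 370 higher and 335 lower of 2141 (median 0.01), and so were the broadly expressed genes, with 11.1% higher and 11.8% lower of 5052 (median -0.02). Of 2526 brain-enriched genes tested in ovary, 509 were higher and 257 lower (median 0.15, camera adjusted p = 0.0251). By fry, adjusted p was 0.0566. The camera call was lost with an estimated correlation (adjusted p = 0.506), without P. formosa fish 11 (adjusted p = 0.1005) and without hybrid fish 10 (adjusted p = 0.0799). Liver-enriched genes had 179 higher and 254 lower of 1441 (median -0.11, camera adjusted p = 0.177).

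Some genes in ovary were counted almost only in 1 genotype. Gene 103149036 had 18.2 ± 1.18 CPM and gene 103142986 had 17.1 ± 0.75 CPM in P. formosa ovary (SD, n = 4), with no count in the 4 hybrid ovaries, at least 1049-fold and 987-fold higher. Gene 103149744 stood at 147 ± 4.15 CPM in hybrid ovary (n = 4) and at 0.1496 ± 0.113 in P. formosa (n = 4). Gene 103135010 had 70.28 ± 6.48 CPM in hybrid ovary (n = 4) and 2 counts over the 4 P. formosa ovaries, a ratio of 6069 with a 95% counting interval from 1680 to 50123. Adjusted p for the 4 genes ran from 2.3e-08 to 7.2e-07 (edgeR quasi-likelihood test). With the library series as a term, 3207 genes were higher and 2845 lower in ovary. Of these, 4572 were called in the same direction without the term. Without P. formosa fish 12 the number of lower genes was 1927.

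In the brain, 1761 genes were higher and 966 lower in P. formosa among 22611 tested (12.1%), and 1238 and 297 of them differed by over 2-fold. Of 2807 brain-enriched genes, 225 were lower and 34 higher in P. formosa brain (median -0.17, camera adjusted p = 4.1e-14, and 0.506 with an estimated correlation). Of the other organs' classes, 182 of 1483 liver-enriched genes were higher and 53 lower (median 0.25, adjusted p = 0.0010) and 203 of 1892 ovary-enriched genes were higher and 36 lower (median 0.17, adjusted p = 0.0019). With an estimated correlation, adjusted p was 0.506 for both of these classes. By fry no class passed in brain (adjusted p = 0.181 for brain-enriched, 0.114 for liver-enriched, 0.0547 for ovary-enriched and 0.452 for broad genes). Broadly expressed genes had 269 higher and 132 lower of 5052 (median 0.05, adjusted p = 0.295). These class differences rested on the P. formosa brains 4 and 11, the libraries that stood apart on the first component. Without them the medians were -0.02 for brain-enriched, 0.02 for liver-enriched and 0.07 for ovary-enriched genes, and none passed the test (adjusted p = 0.115, 0.840 and 0.0865).

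Some single genes also differed in brain. Gene 103132697 had 34.1 ± 3.44 CPM in P. formosa brain (SD, n = 4) and 1 count over the 6 hybrid brains, a ratio of 7364 with a 95% counting interval from 1321 to 290922. It was also at 5.08 ± 0.58 CPM in P. formosa liver and 4.34 ± 0.71 CPM in P. formosa ovary (n = 4 each), against 0.0233 ± 0.0344 (n = 6) and 0.0401 ± 0.0208 CPM (n = 4) in the hybrids. Gene 103154613 had 8.77 ± 5.62 CPM in P. formosa brain (n = 4) and no count in the hybrid brains, at least 617-fold higher. Gene 103149106 had 14.8 ± 3.98 CPM in hybrid brain (n = 6) and 0.303 ± 0.333 in P. formosa brain (n = 4), while in ovary its levels were 21.6 ± 1.29 and 26.1 ± 0.63 CPM (n = 4 each). Gene 103131645 had 8.58 ± 1.01 CPM in hybrid brain (n = 6) and 0.208 ± 0.119 in P. formosa brain (n = 4). Adjusted p for the 4 genes in brain lay between 1.0e-08 and 0.0020 (edgeR quasi-likelihood test).

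The brain counts depended on single fish. Leaving out P. formosa fish 4 gave 826 higher and 420 lower genes, leaving out P. formosa fish 11 gave 1100 higher, leaving out both gave 527 and 378, and leaving out any 1 of the 6 hybrids gave 830 to 1056 higher genes. The number of lower genes was 502 to 624 without any 1 of hybrids 11, 12, 13 or 14. Within the library series with both genotypes the counts were 338 and 279.

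**Figure D3:**
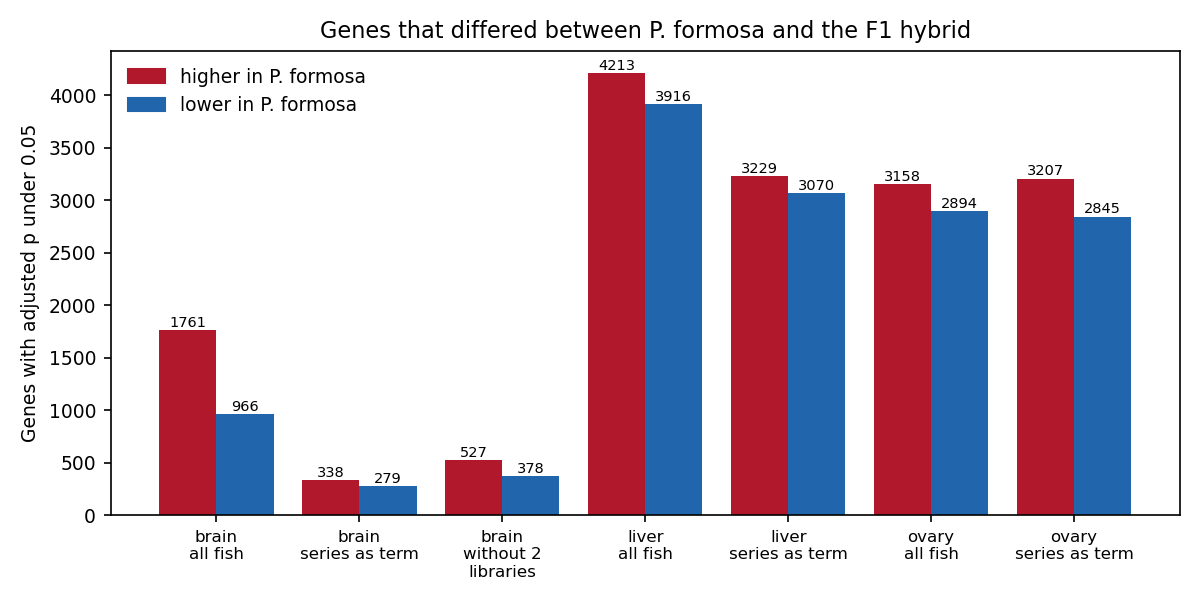
Number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) in P. formosa, by organ, with all fish, with the library series as a term, and for brain also without the P. formosa brains 4 and 11. Liver has 4213 and 3916 genes, ovary 3158 and 2894, and brain 1761 and 966 with all fish.

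A group of genes differed the same way in all 3 organs. Among 16424 genes tested in each organ, 193 were higher and 110 lower in P. formosa everywhere, 303 in all, where independent lists of the same sizes would share 41.8 and 17.6. Another 139 genes were called in all 3 organs with mixed directions. Of the 303 genes, 63.7% were higher in P. formosa (95% exact binomial interval 58.0% to 69.1%, which treats genes as independent). Differences over 8-fold in each organ were found for 22 higher and 10 lower genes. Gene 103142986 had 3.20 ± 2.24 CPM in brain, 3.53 ± 1.07 in liver and 17.1 ± 0.75 in ovary of P. formosa (SD, n = 4 each), and no count in any hybrid library. Gene 103154613 likewise had no count in any hybrid library. Gene 103131645 was at 8.58, 14.0 and 1.64 CPM in hybrid brain, liver and ovary against 0.208, 0 and 0.110 CPM in P. formosa. Gene 103130223 was at 0.660, 0.479 and 3.52 CPM against 0.0073, 0 and 0.0692. With the library series as a term the number of shared genes was 129, and in the main fit it was 175 without P. formosa fish 4 and 200 without P. formosa fish 11. The organs come from the same fish, so the 3 lists are not independent.

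Pairs of organs overlapped unequally. Brain and liver shared 848 higher and 238 lower genes, with 342 and 133 for independent lists, and 128 genes went in opposite directions, with 464 for independent lists. Brain and ovary shared 326 and 187 genes, with 173 and 77.2 for independent lists, and 216 were opposite, with 260 for independent lists. Liver and ovary shared 682 and 633, with 483 and 498 for independent lists, and 700 were opposite, with 983 for independent lists. The organs share fish, so these expected numbers are no test. Across the 16424 genes the fold changes correlated at 0.48 for brain and liver, 0.17 for brain and ovary and 0.18 for liver and ovary, and 1, 2 and 3 of 36 splits of the fish, the real one included, gave a correlation as large. In the same order, the highest of the other splits gave 0.470, 0.171 and 0.205, and the medians of the other splits were 0.277, 0.049 and 0.082. Several of these splits keep part of the genotype contrast.

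A small set of genes was counted in 1 genotype only, taken as at least 1 CPM in every library of a genotype and at most 3 counts over all libraries of the other. Such genes numbered 7 for P. formosa and 2 for the hybrids in brain, 12 and 3 in liver, and 3 and 2 in ovary. Over the organs together, 19 genes met the definition for P. formosa and 7 for the hybrids, and 1 gene met it in all 3 organs, for P. formosa. With 0 counts required in the other genotype, the P. formosa numbers were 3 in brain and 5 in liver, and the hybrid number in ovary was 0.

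The genotype difference itself differed between organs for many genes, as tested by the interaction in a fit of all 28 libraries over 24871 genes. The fit had 1 spread per gene for all organs and no term for the library series. It called 12182 genes between the genotypes in liver and 3246 in ovary, against 8129 and 6052 in the organs' own tests. The interaction counts may therefore depend on the shared fit, which was not tested. The genotype difference differed between liver and ovary for 9376 genes (37.7%), more positive in liver for 5721 and in ovary for 3655. Between brain and liver it differed for 8351 genes (4001 more positive in brain and 4350 in liver). Between brain and ovary it differed for 3032 genes (1968 and 1064), and for 1992 with the fish as a replicate block, since the organs come from the same animals. The balance of directions depended on the method. Between brain and ovary it was 1601 and 1308 with DESeq2 size factors, 2129 and 2109 by the DESeq2 test, and 1590 and 1550 by limma voom with correlated libraries of a fish, and between brain and liver it was 3282 and 4857 with DESeq2 size factors. Between liver and ovary it was 5553 and 3812 with DESeq2 size factors. By the organ contrasts of the first fit, not the organs' own tests, most of the genes that differed in it were called in 1 organ of the pair. These were 7091 of the 8351 genes in liver and not in brain, and 7309 of the 9376 in liver and not in ovary. Called differences in opposite directions accounted for 525 genes between liver and ovary, 143 between brain and liver, and 118 between brain and ovary. Without P. formosa fish 11 the brain and ovary count was 1589.

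The design also allows a comparison of how much siblings differ from each other, between fish of 1 clone and fish of 1 hybrid brood. For each fish the spread was the median over genes of the absolute deviation of log2 CPM from the mean of its genotype. In ovary, clonal siblings were closer to each other than hybrid siblings, at 0.0750 ± 0.0223 (SD, n = 4) against 0.132 ± 0.0204 (n = 4; exact two-sided permutation test, p = 0.0286, the smallest p this design allows, adjusted p = 0.0333 over 3 organs). In liver the values were 0.176 ± 0.0186 (n = 4) and 0.258 ± 0.0575 (n = 6; exact permutation p = 0.0333, adjusted p = 0.0333). In brain the order was the opposite, with 0.196 ± 0.105 (n = 4) for the clone and 0.119 ± 0.0120 (n = 6) for the hybrids (exact permutation p = 0.0333, adjusted p = 0.0333), and P. formosa brain 11 alone was at 0.344. Without that library the difference in brain changed sign, to -0.017 (exact permutation p = 0.143). The threshold was also missed in brain without P. formosa fish 12 or any 1 hybrid except fish 13 (exact permutation p from 0.0635 to 0.0873), in liver without P. formosa fish 4, 11 or 12 or hybrid fish 4 or 10 (p from 0.0595 to 0.151), and in ovary without any 1 hybrid (p from 0.0857 to 0.114). When the deviations of hybrids were taken within their library series, the difference of P. formosa minus hybrid went from -0.082 to 0.00086 in liver (permutation p = 0.981) and from -0.057 to -0.0060 in ovary (permutation p = 0.886). In brain it went from 0.076 to 0.0997 (permutation p = 0.0190). Within a series of only hybrids 4 and 10, or in ovary 12 and 13, both fish get the same value. The permutation counts them as separate fish, so these p-values are not exact. The other p-values of this comparison are only approximate, since fish of a group share the mean from which their deviations were taken.

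**Figure D4:**
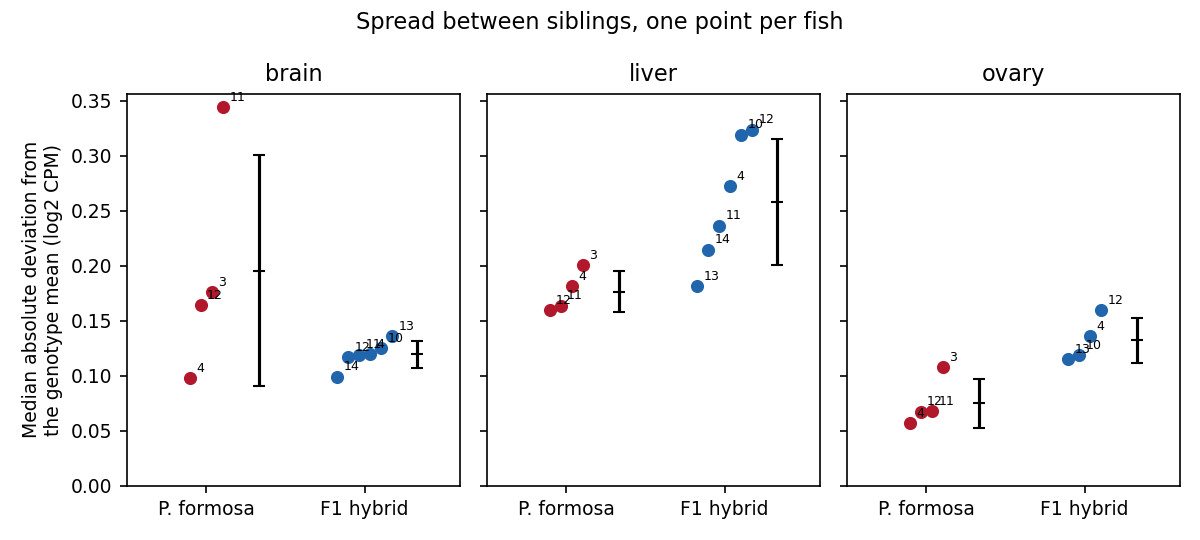
Spread of each fish around the mean of its genotype, as the median over genes of the absolute deviation in log2 CPM, by organ; colored points are fish with their numbers, and the black marks are the mean and SD of each group. The means of the hybrids lie above those of the clone in ovary (0.132 against 0.0750) and liver (0.258 against 0.176), with fish of the groups overlapping in liver, and in brain P. formosa fish 11 lies highest at 0.344. With deviations taken within the library series the difference is 0.00086 in liver, -0.0060 in ovary and 0.0997 in brain.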

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

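Of the tests below, that of depth for the brain libraries and those of the abundant liver and ovary transcripts were chosen after their results had been seen. Among 55 groups of 4 to 6 libraries, 4 held a library far from the others, where chance gives about 1 in 20. The total of P. formosa brain 4 was 34739192 counts against 36514050 to 36785632 in the other P. formosa brains. Liver of hybrid fish 12 had 19.8% of its counts in its most counted gene, against 6.29% to 10.1% in the other hybrid livers, and 41.4% in its 10 most counted genes, against 25.6% to 30.8%. Gene 103142986 was at 1.94 CPM in P. formosa liver 3 and at 3.88 to 4.19 CPM in the other P. formosa livers.

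The effect of genotype differed between organs by the interaction test for 8351 genes between brain and liver, 3032 between brain and ovary and 9376 between liver and ovary. In 1 of 40 drawn splits of the fish, the real one, each count was as large, so a chance split of the fish is excluded at the 0.05 level. The highest counts of the other splits were 1749, 1003 and 2338. Both 1003 and 2338 came from the split that sets hybrids 4, 10, 12 and 13 apart, which in ovary is the genotype contrast itself. The organ counts stood out in the same way. Of 100 drawn splits of the 10 brain libraries, 1 gave as many genes as the real split (2727), and the highest other gave 191. Of 100 drawn splits of the 10 liver libraries, 1 gave as many as the real 8129, and the highest other gave 5415. Of the 35 splits of the 8 ovary libraries, 1 gave as many as the real 6052, and the highest other gave 0.

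P. formosa brains 4 and 11 stood apart from P. formosa brains 3 and 12. Their brain-enriched genes had medians 0.14 and 0.52 lower on the log2 scale, and liver-enriched genes had medians 0.33 and 0.35 higher. Their totals are no explanation, since both (2 of 2) lay within the range of the other 8 brain libraries. Liver or ovary tissue in the dissection may have added to the higher classes: the smallest of the 4 class medians, 0.0938, lay under the bound set against this, but the other 3, at 0.22 to 0.35, lay above it and below the bound set for it. As the cause of the lower brain-enriched genes, whose median fall needs a share of 30.2% in fish 11 and 9.55% in fish 4, such tissue is argued against for liver and ovary in fish 11 and for ovary in fish 4: the 50 most abundant genes exceeded the other brains by 0.997%, 0.431% and 0.209% of their level in the source organ. Liver tissue in fish 4, with 1.23%, stays open, as do other tissues, cell make-up and the state of the fish, which were not tested.

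Hybrid libraries of the 2 library series differed within organs, by 269 genes in brain and 1733 in liver (2 against 4 fish) and 1010 in ovary (2 against 2 fish). The split of all fish that sets hybrids 11 to 14 apart, as the series does, gave 191 genes in brain and 5415 in liver, where the 11 other drawn splits that set 4 hybrids apart gave at most 1 and 3. Depth is argued against: after thinning the hybrid ovaries to 1 total, 99.5% of the genes called between the series in ovary kept their call and direction. A batch in library preparation might move the same genes in every organ: across 7013 genes, the series difference correlated at 0.279 between brain and liver, but 3 of the 15 ways to part 2 hybrids from 4 gave a value as large and the highest was 0.317, while brain and ovary gave 0.295 (highest of 3 ways, next 0.164) and liver and ovary 0.031 (highest other 0.075). By the bound set beforehand, a value not above the other splits, this counts against a batch, but the margin is smaller than the SD of the other splits (0.0985), a yardstick added after the value was seen, and the series holds only hybrids 4 and 10 beside the clone, so batch and differences between hybrid sisters cannot be told apart.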

How the results depend on the processing

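The gene counts with hybrids of the second series only or without P. formosa brains 4 and 11, the spread with deviations within series, the class tests, and the shared genes with a block or a fish left out were chosen after seeing the data; the cause was not tested where none is named. Among the single genes given by ID, 5 of 438 values under the alternatives lost the threshold and none changed direction. These genes were picked for their large differences, so this says little about the other called genes. Of the 8 class calls by camera, all 8 were lost at an estimated correlation, and 14 of 128 values by camera over all alternatives lost the threshold. With classes cut at an 8-fold margin, the median of the ovary-enriched class was 1.21 in liver and 0.27 in brain, in place of 0.69 and 0.17. Counts are given as higher and lower in P. formosa. DESeq2 gave 2773 and 1819 in brain and 467 shared genes. Limma voom gave 926 higher in brain. The library series as a term gave 338 and 279 in brain and 129 shared genes. A tested change of over 2-fold, a stricter question, gave 216 and 89 in brain, 1632 and 738 in liver, and 907 in ovary (514 and 3.9e2). At an adjusted p of 0.01, fewer genes pass by construction: 720 in brain (4.5e2 and 269), 2490 lower in liver, 1803 and 1401 in ovary, and 102 shared. A fit of all 28 libraries gave 494 lower in brain, 7215 higher in liver, and 1641 and 1605 in ovary. Fish with all 3 organs, which are fewer, gave 503 and 357 in brain and 143 shared. Hybrids of the second series alone, where genotype and series cannot be told apart, gave 844 higher in brain and 4656 lower in ovary. Without P. formosa brains 4 and 11, brain had 527 and 378.

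Leaving out each fish in turn gave 826 to 2531 higher and 420 to 1089 lower genes in brain, 3413 to 4349 and 3005 to 4058 in liver, 2366 to 3227 and 1927 to 3175 in ovary, and 175 to 306 shared genes. Interaction counts were 6605 to 8372 for brain and liver, 1589 to 2944 for brain and ovary, and 7685 to 9265 for liver and ovary. The difference in sibling spread ran from -0.017 to 0.121 in brain, from -0.102 to -0.064 in liver and from -0.075 to -0.039 in ovary.

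Numbers shared by P. formosa and hybrid fish do not pair them: deviations of same-numbered fish correlated at -0.09 to 0.17 in brain, 0.03 to 0.07 in liver and -0.18 to 0.09 in ovary. The replicate block, which keeps few residual degrees of freedom, gave 91 and 40 in brain, 2773 and 2295 in liver, 355 and 228 in ovary, and 15 shared genes. With the fish as a block in the interaction, where organs are paired, the brain and ovary count was 1992, and no other interaction count moved by over 1.5 times.

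The difference in spread between siblings (P. formosa minus hybrid) was 0.080 in brain and -0.030 in liver with hybrids of the second series only (exact permutation p = 0.114 and 0.371). With deviations taken within series it was 0.00086 in liver, -0.0060 in ovary and 0.0997 in brain. Without P. formosa brain 11 it was -0.017 in brain. No count was found for 3888 genes, whether for lack of depth or of expression. Liver recovered 23 of 100 simulated 2-fold changes, the fewest of the organs, though its libraries were deeper than those of brain. The simulation changed far fewer genes than were called in the data, so this does not measure power there.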

Other observations

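Of the tests in this part, the shares of shared genes with a fish left out were chosen after the data were seen. Genes that differed the same way in all 3 organs numbered 303, and 1 of 36 drawn splits of the fish, the real one, gave as many, with 0 in the highest other. This is no test of sharing between organs. In ovary alone every split other than that of the genotypes gave 0 genes, so such splits could share none.

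The shared genes have candidate explanations that need no change in regulation. Hybrid reads may map less well to the reference used, which would leave most shared genes higher in P. formosa. Of them, 63.7% were, with an interval from 58.0% to 69.1% that includes the 60% set as the bound. The share ran from 56.5% without P. formosa fish 11 to 71.9% without P. formosa fish 3 when a fish was left out. Over the alternatives fixed beforehand it ran from 53.9% at an adjusted p of 0.01 to 63.6% without a filter. Poorer mapping of hybrid reads thus stays open. A plain loss of hybrid reads would not leave genes lower in P. formosa, as the 110 lower genes were. Reads shared between gene copies, or a reference that takes up the groups unequally in other ways, were not tested. Neighbouring genes may change together: 9 pairs of the shared genes lay on adjacent lines of the table, where 10000 shuffles gave 3.44 on average (permutation p = 0.0066), and 8 of the 9 pairs went the same way. Whether the order of the table follows the genome was not tested, and these pairs hold few of the 303 genes. Genetic differences between the clone and the brood, such as alleles of the parental species or lost genes, stay open and were not tested.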
